A study of Capra hircus with 2 samples.

How the data were processed

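The series profiled fetal goat (Capra hircus) ovary by droplet single-cell RNA sequencing at embryonic day 85 (E85) and embryonic day 125 (E125), with 1 library per stage and 2 libraries in all. Per the labels' protocols, the tissue was dissociated with enzymes and libraries were made with a 10x 3' kit of version 3.1, which tags each captured molecule with a unique molecular identifier (UMI). The text of that protocol speaks of testes, while the tissue and sex labels of both samples say ovary and female, and the labels were followed. The authors deposited UMI counts per gene and cell barcode, whole numbers with no normalization, as gene, barcode and value matrices. The submitters' processing notes name Cell Ranger 3.1, whereas the deposited count matrices name Cell Ranger 6.0.0 per the file headers. The genome build and gene annotation are not given in the sources used here. The deposited counts were of barcodes already called as cells, with at least 500 UMIs each in both libraries. The files list 27271 features by goat Ensembl identifier, of which 10655 (39.1%) carry no symbol and were kept under their identifier. Those features held 39.1% of UMIs at E85 and 35.5% at E125. A separate table of RefSeq names gave no Ensembl identifiers, so 0 identifiers were matched through it and symbols come from the deposited files alone. Another 43 symbols stood on more than 1 feature. Several familiar genes, among them FOXL2, NOBOX, COL3A1 and FOXO3, have no feature under that symbol, and their values are not analysed here.

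Barcodes with fewer than 500 genes or more than 20% of UMIs from the 13 mitochondrial genes were left out, 425 at E85 and 809 at E125. The threshold that Scrublet sets for itself called 2 and 0 barcodes, so the caller had not worked in that form. The barcodes with the highest Scrublet scores, 0.8% per 1000 barcodes, were therefore removed, 155 (3.53%) at E85 and 557 (6.67%) at E125, and some doublets will remain. This kept 3825 and 7023 cells, with median depths of 3102 and 3193 UMIs. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen across both libraries, and 30 principal components and 15 neighbours gave Leiden clusters at resolution 1, with both libraries clustered together and no integration. Markers of 11 cell classes were fixed before the data were examined, as were the 20 gene lists, the rule for named genes, the comparisons and most of the alternative settings. The rule that turns markers into names was not fixed. In all, 4 naming rules were tried after the clusters were seen, and the rule used was picked by looking at the names it gave. It divided each marker's CPM (the count scaled by the summed counts of the cells it comes from) in a cluster by the highest CPM of that marker over the clusters of the same library, leaving out markers under 20 CPM everywhere. A cluster of 15 or more cells in a library took the class with the highest mean share, if that mean was at least 0.3 and at least 3 markers reached 0.25. Other clusters stayed unnamed, and smaller parts took the class of the cluster's part in the other library. The largest E125 stromal-like cluster passed with a mean share of 0.303, just above the limit. The other 3 rules gave 49, 120 and 49 germ-cell-like cells at E85 where the rule used gave 49, and 129 at E125 under all 4. They gave 314, 243 and 314 pregranulosa-like cells at E85 where the rule used gave 243, and 588 at E125 under all 4. Stromal-like cells at E125 numbered 4765, 1940 and 4801 under those 3 rules and 4765 under the rule used. Unnamed cells numbered 220, 223 and 220 at E85 and 36, 2861 and 101 at E125 under those rules, against 291 and 36. A difference from the study's own account may come from these rebuilt names.

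UMI counts were summed per class and library and divided by the class total to give CPM. With 1 library per stage there is no spread between animals, so no test was run, no p-value is given, and every difference describes these 2 libraries. Sums carry exact Poisson 95% intervals, ratios of sums exact conditional 95% intervals, and shares exact binomial (Clopper-Pearson) 95% intervals. All of these cover counting error only. Ratios are E125 over E85 unless said to be lower, and a count of 3 UMIs or fewer was replaced by a floor of 3 in the class sum of that library. A fold that rests on 2 UMIs or fewer is thus smaller than that of the counts themselves and is given as at least. It is not a 95% bound, which can lie lower, and intervals where given are those of the counts themselves. A gene was measured with 50 or more summed UMIs and counted as higher or lower at 2-fold. Classes other than the 3 main ones (germ-cell-like, pregranulosa-like and stromal-like) were compared if both libraries held 50 or more cells. Named genes were the 10 highest and 10 lowest ratios in the germ-cell-like and pregranulosa-like classes, and the 5 highest and lowest in others. They needed a symbol, 50 CPM in at least 1 library, and a level of at least 0.2 of that in the class where the gene was highest. This leaves out genes that free RNA from a class with a far higher level could carry in. A gene with like CPM in all classes passes, so named genes are not cleared of free RNA. Mitochondrial, ribosomal protein and haemoglobin genes were not eligible, and 1 gene that met the rule in pregranulosa-like cells is not reported here. Of each gene list, members with the most UMIs and those past 2-fold may also be named. The median log2 ratio of a list was taken over members with 20 or more summed UMIs and placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Several list members are also naming markers, such as DDX4, FIGLA and ZP3 for germ cells and FST, AMH, INHA and HSD17B1 for pregranulosa cells. Shares of cells with a UMI of a stage marker were taken after thinning each cell to 2000 UMIs. The gene lists were germ mitotic or pluripotency, germ meiotic entry, germ meiotic prophase, germ oocyte, piRNA pathway, apoptosis, cell cycle, Notch, TGF-beta and BMP, KIT and PI3K, pregranulosa regulators, follicular granulosa, WNT, steroidogenesis, cholesterol synthesis, extracellular matrix, dissociation stress, glycolysis, oxidative phosphorylation, and testis supporting or Leydig.

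The ratio step was tested on Poisson counts simulated from the pooled proportions of each class, with 200 genes set 4-fold apart. It recovered 87.5% of them over 8993 genes in germ-cell-like cells, 85.5% over 7415 in pregranulosa-like cells and 94.5% over 10216 in stromal-like cells. Equal numbers were set higher and lower at E125, but fewer lower genes were recovered. These were 75 lower against 100 higher in germ-cell-like, 72 against 99 in pregranulosa-like and 89 against 100 in stromal-like cells. Splits of higher against lower genes therefore lean toward higher ones, and the other classes were not simulated. Among genes simulated without a difference, 1.58%, 0.939% and 0.110% passed 2-fold in those classes. Intervals held the true ratio for 95.9%, 96.0% and 95.8% of genes. The simulation held no spread between cells, animals or libraries. These values therefore cover counting error alone and give no error rate for the counts of genes past 2-fold in the real libraries. Alternatives covered edgeR TMM and DESeq2 size factors on the class sums, the mean over cells, thinned cells, UMI minimums of 20 and 200 (50 for lists), genes that free RNA could carry left out, no cell filter, a stricter filter of 1000 genes and 10% mitochondrial UMIs, no doublet removal, resolutions of 0.5 and 2, and separate clustering. Added after the data were seen were the 3 other naming rules, germ-cell-like droplets of 20000 or more UMIs alone, pregranulosa-like cells without a small E125 cluster, and gene counts and lists under the other clusterings. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, with the random seed set to 0.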

Results

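Single-cell transcriptomes of fetal goat ovary were collected at E85 and E125, the period in which germ cells and pregranulosa cells assemble into primordial follicles, with 1 library per stage. The E85 library held 4397 barcodes and 17748948 UMIs, with a median of 2991 UMIs and 1127 genes per barcode. The E125 library held 8346 barcodes and 49692252 UMIs, with a median of 3044 UMIs and 1232 genes. Depth per barcode ran from 500 to 214449 UMIs at E85 and from 500 to 283741 at E125, and 17910 and 19434 genes were detected. After filtering, 3825 and 7023 cells entered the comparisons. There were no replicates at either stage, so differences between the libraries cannot be set against a spread between animals.

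The first comparison asked which cell classes made up the ovary at each stage. Stromal-like cells formed 72.7% of kept cells at E85 (95% interval 71.2 to 74.1) and 67.8% at E125 (66.7 to 68.9), the latter 48.8% at resolution 2 and 27.6% under a naming rule by fold over other clusters. In the main setting endothelial-like cells had the widest gap among the larger classes, 2.22% at E85 (1.78 to 2.74) and 10.8% at E125 (10.0 to 11.5). The stromal-like gap was wider at resolution 2 and under that naming rule. Germ-cell-like cells were 1.28% (0.949 to 1.69, 49 cells) and 1.84% (1.54 to 2.18, 129 cells). That order turned to 3.14% and 1.87% with separate clustering, 2.75% and 1.87% at resolution 0.5, 3.63% and 3.07% without a cell filter and 3.14% and 1.84% under that naming rule, so none is read. Pregranulosa-like cells, the somatic partners of oocytes, were 6.35% (5.60 to 7.17, 243 cells) and 8.37% (7.73 to 9.04, 588 cells), an order that turned to 6.35% and 4.81% at resolution 2 and 6.25% and 3.49% with separate clustering and is not read either. Surface-epithelium-like cells were lower at E125, 5.01% (4.51 to 5.55) against 6.85% (6.07 to 7.70), and the E125 share was 1.16% with the stricter filter, 2.02% with none and 3.15% at resolution 2. Perivascular-like cells stood at 0.863% and 1.75%, myeloid-like cells at 1.39% and 1.42%, lymphoid-like cells at 0.732% and 1.44%, and glia-like cells at 0.0523% (2 cells) and 1.05%. Glia-like cells turned to 2.27% and 1.05% at resolution 2 and 2.33% and 1.05% with separate clustering, and lymphoid-like cells to 2.22% and 1.44% with separate clustering and 0 in both at resolution 0.5, so neither order is read. No cluster was named steroidogenic-like or erythroid-like. Classes were given to whole clusters, so 0 cells set no upper limit on the share of such cells. The lack of steroidogenic-like cells depended on the clustering. At resolution 2, 359 E125 cells were steroidogenic-like, and 341 with the libraries clustered separately. E125 pregranulosa-like cells then numbered 338 and 245 instead of 588. Unnamed clusters held 7.61% of E85 cells (6.79 to 8.49) and 0.513% of E125 cells, but 7.58% and 19.9% at resolution 2 and 5.83% and 40.7% under the naming rule by fold over other clusters, so no order is read. At E85 these were clusters 12 (5.75%) and 17 (1.86%), and at E125 cluster 21, led by the interferon-induced genes ISG15, MX1 and IFIT1. All germ-cell-like cells fell in cluster 13 in both libraries. Pregranulosa-like cells came from cluster 11 at E85 (242 of 243, led by TRIB2, FST and ALPL) and mainly from cluster 7 at E125 (539 cells, led by SYT6, KCNK12 and STC1). Another 44 E125 pregranulosa-like cells, led by HSD17B1, FST, AMH and INHA, were the E125 part of cluster 17, whose E85 part of 71 cells, led by KRT17, CDKN1A, ASB9 and ZP4, stayed unnamed. Stromal-like cells came mainly from clusters 2 and 5 at E85 (1883 and 708 cells) and clusters 1, 3 and 6 at E125 (2825, 984 and 655 cells), each mostly of 1 library, so these clusters may mark the library rather than a cell type. The same holds for the pregranulosa-like clusters 11 and 7, each almost wholly of 1 library.

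**Figure D1:**
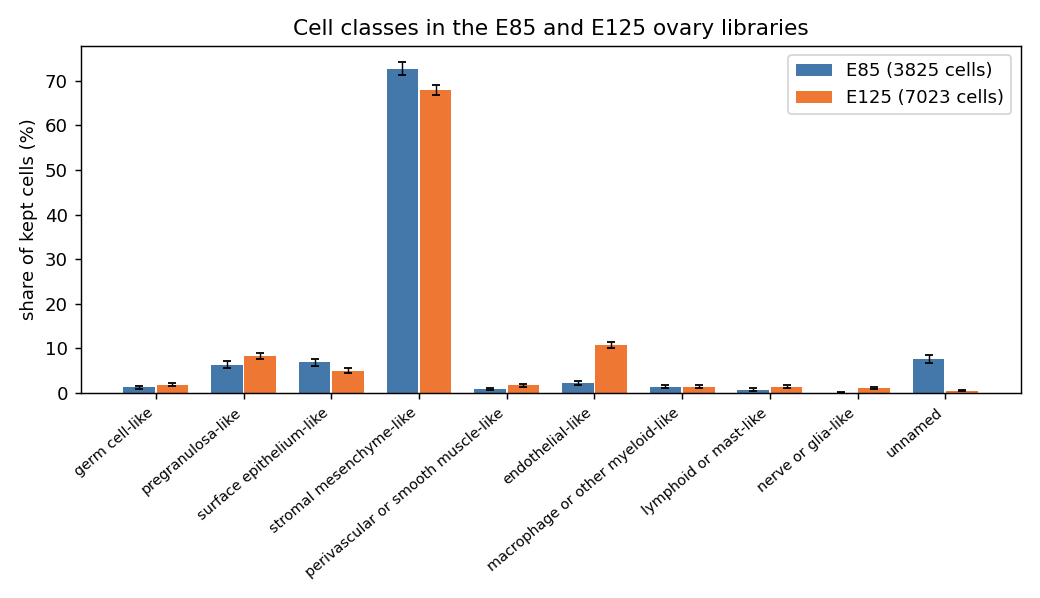
Share of kept cells (y axis, %) in each cell class (x axis) for the E85 and E125 libraries, with error bars giving exact binomial 95% intervals that cover counting error only. Endothelial-like cells stand at 2.22% and 10.8% and stromal-like cells at 72.7% and 67.8%.

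Germ-cell-like droplets ran from 743 to 214449 UMIs at E85 and from 666 to 283741 at E125. Droplets of 20000 or more UMIs, a limit set after these numbers were seen, made up 22 of 49 at E85 (44.9%, 30.7 to 59.8) and 71 of 129 at E125 (55.0%, 46.0 to 63.8). Among these large droplets the median was 56361 UMIs at E85 and 139940 at E125, a ratio of 2.48. The ratio depended on the limit, at 2.48 for 10000 UMIs and 1.45 for 40000 (12 and 67 droplets). The smaller droplets had medians of 2570 and 1889 UMIs. Over all germ-cell-like droplets the medians were 8568 and 52865, a ratio of 6.17 that mixes large and small droplets. Median UMIs per cell differed far less in other classes, with ratios of 1.39 in pregranulosa-like, 0.784 in surface-epithelium-like, 1.04 in stromal-like, 1.01 in endothelial-like and 0.642 in myeloid-like cells. The 10 largest germ-cell-like droplets supplied 69.3% of the class UMIs at E85 and 23.7% at E125, so E85 germ-cell-like sums rest on few cells.

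**Figure D2:**
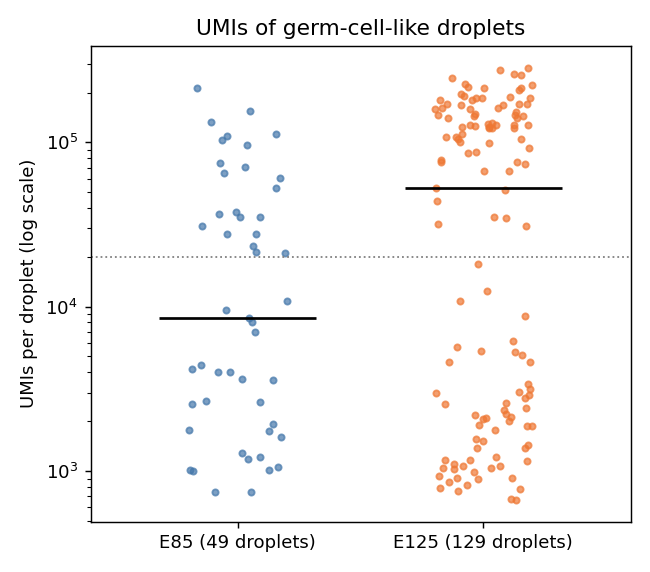
UMIs per germ-cell-like droplet (y axis, log scale) in the E85 and E125 libraries, where each point is a droplet, black bars mark medians and the dotted line marks 20000 UMIs. The medians are 8568 and 52865 UMIs, and 22 of 49 and 71 of 129 droplets lie at or above the line.

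The next comparison asked which genes differed in germ cells between the stages. HES7, a bHLH repressor of the Hes family, went from 0 to 2086 UMIs, at least 112-fold higher, and KISS1, which encodes kisspeptin, from 0 to 1945 UMIs, at least 105-fold higher. C4orf48 stood at 1.84 CPM and 249 CPM, 136-fold higher (46.4 to 659, from 3 UMIs at E85), and was among the named higher genes of 4 classes, so neither it nor any gene named in several classes is specific to germ cells. The homeobox genes NKX6-2, DBX1 and NKX1-1 were 61.4-fold (21.0 to 298), at least 59.3-fold (24.6 to 735) and at least 35.6-fold (19.1 to 4223) higher, from 3, 2 and 1 UMIs at E85. AMN, which encodes amnionless, a partner of the endocytic receptor cubilin, had 7.96 CPM and 306 CPM, 38.5-fold higher (22.5 to 72.3). ANKRD9, CCDC3 and PODXL2 completed the named genes, at least 68.5-fold (36.8 to 8127), at least 36.3-fold (15.0 to 450) and 32.9-fold (11.2 to 160) higher from 1, 2 and 3 UMIs. Lower at E125 were the tubulin gene TUBB2B, 187-fold (84.3 to 517, and among the named lower genes of 5 of the 6 compared classes), the neural splicing regulator PTBP2, 7.59-fold, and PDCD4, a repressor of translation, with 184 CPM and 30.2 CPM, 6.08-fold (5.17 to 7.15). TMEM38B, PRPF39, SNX4, CCP110 and ART3 were 6.58-, 6.24-, 5.94-, 5.92- and 5.76-fold lower, the purine salvage enzyme gene APRT 5.64-fold and the tRNA exporter gene XPOT 5.59-fold.

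In germ-cell-like cells, 1776 of 8988 measured genes were at least 2-fold higher at E125 and 1645 at least 2-fold lower, by the rule of size alone. That rule missed more lower than higher genes in simulated counts, so the split leans toward higher genes. Higher genes were 51.9% of both, 67.7% with TMM (2253 and 1074), 67.1% with DESeq2 size factors (2226 and 1092) and 64.4% with the mean over cells (2957 and 1638), which moved the median log2 ratio of all genes up by 0.26, 0.25 and 0.37. Some genes differed alike in every compared class. Of 1804 genes measured in all 6 classes, 69 were at least 2-fold higher and 30 at least 2-fold lower in each, which is not specific to germ cells. With 1 library per stage, a technical difference between the libraries is not excluded as the source of these. TAF10, a subunit of the transcription factor TFIID, was 14.1- to 35.8-fold higher across the classes, SMAP1 14.3- to 28.1-fold, KLF13 7.39- to 25.4-fold, the small GTPase gene RAC1 4.35- to 8.55-fold and JUN 4.25- to 10.8-fold. COX8A, a subunit of cytochrome c oxidase, was 2.79- to 7.39-fold lower, APRT 2.81- to 5.64-fold and NEDD8, a ubiquitin-like modifier, 2.29- to 6.50-fold.

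The piRNA and meiotic lists had negative medians in E125 germ-cell-like cells, with part of their members past 2-fold, and the oocyte list a positive one. These medians compare shares of the class total, not molecules per droplet. Large germ-cell-like droplets held a median of 56361 UMIs at E85 and 139940 at E125. A lower share therefore need not mean fewer molecules of a gene per droplet. RNA quality may enter the list medians too, since the median mitochondrial share of the class was 5.43% at E85 and 1.90% at E125. With the stricter filter, which allows 10%, the piRNA median was -1.33 and that of meiotic prophase -0.63. The piRNA pathway, which silences transposons, had a median log2 ratio of -1.38 (percentile 0), with 0 higher and 11 lower of 14 measured. DDX4, the germ cell RNA helicase, had 369 CPM at E85 and 113 CPM at E125, 3.28-fold lower, TDRD1 243 and 70.1 CPM, 3.47-fold lower, and TDRKH and ASZ1 were 5.34- and 5.68-fold lower, whereas MAEL stayed at 410 and 371 CPM. Meiotic prophase genes had a median of -0.88 (percentile 0.1), with 0 higher and 10 lower of 24. SPATA22, needed for meiotic recombination, had 108 and 27.2 CPM, 3.97-fold lower, and the synaptonemal complex genes SYCP1, SYCE1, SYCE2 and TEX12 were 2.56-, 4.6-, 2.80- and 3.11-fold lower, while SMC1B, REC114 and HSF2BP stood at 357 and 254, 231 and 238, and 221 and 206 CPM. Meiotic entry genes had a median of -0.79 (percentile 7.69), with 0 higher and 2 lower of 5: STRA8, the retinoic acid responsive gate to meiosis, was 14.5-fold lower on 21 and 9 UMIs, TUBA3D was 2.92-fold lower, and REC8 had 922 and 785 CPM. Oocyte genes had a median of 0.38 (percentile 96.9), with 5 higher and 1 lower of 20, and the size of that median is loose, at 1.45 with the mean over cells and 0.84 in thinned cells. FIGLA, a transcription factor of zona pellucida genes, had 735 CPM and 3653 CPM, 4.97-fold higher (4.69 to 5.27), and ZAR1, NLRP9, BMP15 and ASTL were 5.85-, 4.31-, 4.03- and 2.10-fold higher. GDF9 was 2.81-fold lower on 19 and 42 UMIs, and ZP3, the most abundant member, stood at 8876 and 9640 CPM. FIGLA and ZP3 also lead the germ-cell-like cluster in both libraries.

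Lists of bone morphogenetic protein (BMP) and WNT pathway genes and of somatic regulators also had positive medians in germ-cell-like cells at E125, with the larger part of the pathway genes within 2-fold. Somatic RNA was present in these droplets. The median pregranulosa marker reached 0.595 of its UMIs per pregranulosa-like cell, and the median stromal marker 0.549 of its UMIs per stromal-like cell. Part or all of these list values may therefore be somatic. TGF-beta and BMP genes had a median log2 ratio of 0.39 (percentile 96.9), with 9 higher and 1 lower of 32, and 1.18 with the mean over cells. ID3, a BMP target, was 2.65-fold higher (84.5 and 224 CPM), ID1 13.3-fold (4.51 to 65.1, from 3 UMIs) and TGFB2 14.8-fold (5.01 to 72.1, from 3 UMIs). WNT genes had a median of 0.79 (percentile 99.6), with 8 higher and 0 lower of 20, among them SFRP2 (30.6 and 89.2 CPM) and WNT5A (11.6 and 39.9 CPM). Pregranulosa regulators had a median of 1.14 (percentile 99.9), with 7 higher and 2 lower of 14: EMX2 had 9.19 and 51.1 CPM, NR0B1 7.96 and 45.6 CPM and IRX5 2.45 and 23.5 CPM, while CTNNB1 and LHX9 were 2.43- and 3.72-fold lower. Somatic cells held the same genes at higher levels, with EMX2 at 243 CPM and IRX5 at 197 CPM in surface-epithelium-like cells at E125, WNT5A at 399 CPM and SFRP2 at 308 CPM in stromal-like cells, and ID1 at 2876 CPM in endothelial-like cells. Notch genes had a median of 0.64 (percentile 98.6), with 4 higher and 0 lower of 12, among them HES1, 4.34-fold higher (9.80 and 42.6 CPM), while the ligand gene JAG1 had 390 and 252 CPM. In cells thinned to equal depth the Notch median was -0.0044, so no direction is read from it. Extracellular matrix genes had a median of 0.53 (percentile 95.2), with 6 higher and 2 lower of 20, and the matrix gene SPARC stood at 82.7 and 273 CPM. That median turned to -0.99 under a naming rule that put more E85 cells in the class, -1.02 at resolution 0.5 and -0.92 with separate clustering, so no direction is read from it. Steroidogenesis genes had a median of 0.72 (percentile 94.1), but 0.13 under that naming rule, with 3 higher and 0 lower of 6, including STAR, the cholesterol carrier of mitochondria, 2.34-fold higher (58.8 and 138 CPM), and FDX1, at least 26.0-fold higher (10.7 to 323, from 2 UMIs).

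The remaining lists in germ-cell-like cells follow. Mitotic or pluripotency genes had a median of 0.41 (percentile 79.5), with 1 higher and 0 lower of 4. SALL4, a germline zinc finger gene, was 2.19-fold higher (143 and 312 CPM), and POU5F1 had 39.2 and 19.7 CPM. KIT and PI3K genes had a median of 0.16 (percentile 80), with 1 higher (RHEB, 2.09-fold) and 1 lower (RPS6KB1, 3.68-fold) of 14, and follicular granulosa genes 0.27 (percentile 73.9), with 0 past 2-fold of 9 (-0.59 under a naming rule that put more E85 cells in the class, -0.39 at resolution 0.5 and -0.37 with separate clustering). Apoptosis genes had a median of -0.56 (percentile 15.7), with 1 higher and 3 lower of 11. BCL2L11, which encodes BIM, was 3.56-fold higher, and APAF1, BAX and XIAP were 3.15-, 3.81- and 4.53-fold lower. Cell cycle genes had a median of -0.34 (percentile 22.9), with 2 higher and 4 lower of 20, and cholesterol synthesis genes -0.29 (percentile 36.6), with 1 higher and 4 lower of 13. With the mean over cells the medians of these 3 lists were positive, at 0.30 for apoptosis, 0.36 for cell cycle and 0.30 for cholesterol synthesis. Oxidative phosphorylation genes had a median of -0.41 (percentile 4.33), with 0 higher and 2 lower of 15 (COX8A and SDHC), glycolysis genes 0.22 (percentile 75.0), with 0 higher and 1 lower (PGK1) of 8 (-0.58 under that naming rule, -0.52 at resolution 0.5 and -0.57 with separate clustering), and testis supporting or Leydig genes -0.87 (percentile 10.3), with 0 higher and 2 lower of 4, among them DMRT1 at 92.5 and 42.9 CPM. Dissociation stress genes, which respond to enzymatic handling, had a median of 0.47 (percentile 90.8), with JUN and DUSP1 8.28- and 3.20-fold higher and HSPA8 and HSPH1 3.84- and 2.43-fold lower of 9. The median of that list was -1.18 in thinned cells, -0.28 under the same naming rule, -0.29 at resolution 0.5 and -0.28 with separate clustering.

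**Figure D3:**
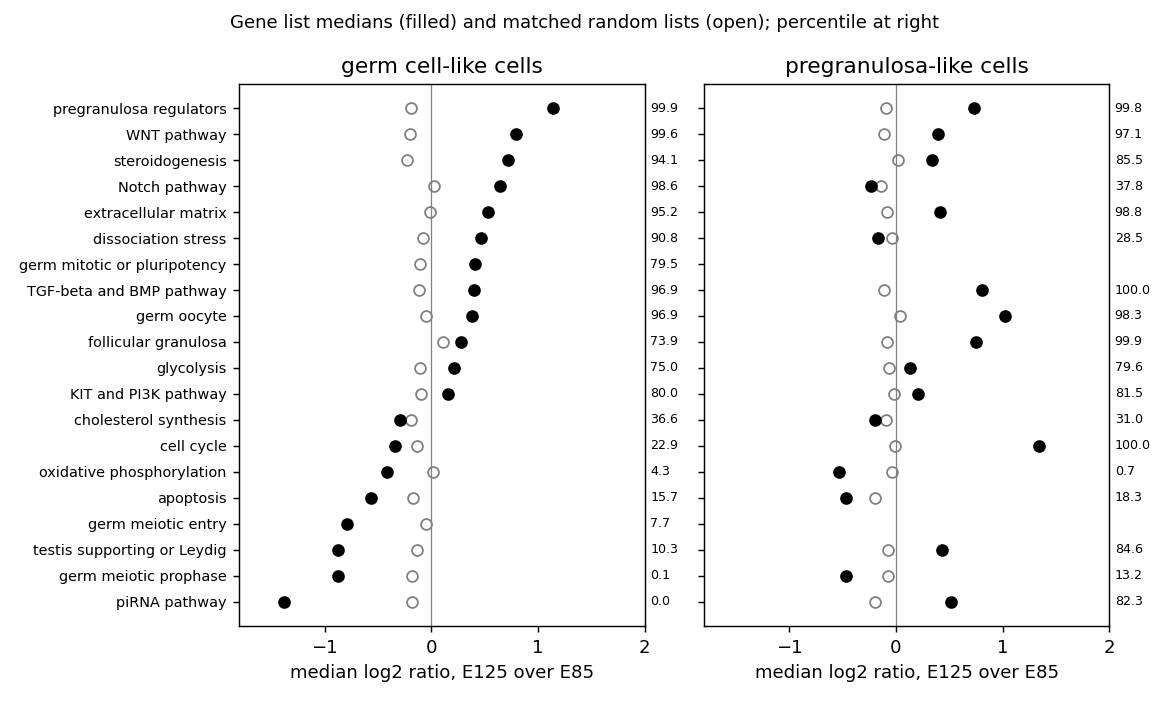
Median log2 ratio of E125 over E85 (x axis) for each gene list (y axis) in germ-cell-like and pregranulosa-like cells, where filled points are the lists, open points the median of matched random lists, and the number at the right the percentile among them. In germ-cell-like cells the piRNA list lies at -1.38 and the pregranulosa regulators at 1.14, and in pregranulosa-like cells the cell cycle list lies at 1.34.

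Shares of germ-cell-like cells with a UMI of a stage marker were compared at an equal depth of 2000 UMIs, over 36 cells at E85 (13 shallower cells left out) and 98 at E125 (31 left out). FIGLA was detected in 63.9% of E85 cells (46.2 to 79.2) and 99.0% of E125 cells (94.4 to 100), and ZP4, a zona pellucida gene, in 25.0% (12.1 to 42.2) and 88.8% (80.8 to 94.3). ZP3 was detected in 83.3% and 100% (96.3 to 100) and UCHL1 in 72.2% and 89.8%. The meiotic cohesin gene SMC1B had the opposite order, 58.3% (40.8 to 74.5) and 32.7% (23.5 to 42.9). Without thinning the shares were 65.3% and 95.3% for FIGLA, 22.4% and 82.9% for ZP4, 93.9% and 100% for ZP3, 79.6% and 87.6% for UCHL1, and 81.6% and 69.0% for SMC1B, at median depths of 8568 and 52865 UMIs. In thinned stromal-like cells, which should lack these genes, FIGLA was seen in 0.948% and 6.78%, ZP3 in 4.74% and 20.4%, ZP4 in 0.569% and 3.85% and UCHL1 in 18.2% and 16.9%, at median depths of 2758 and 2861 UMIs before thinning. Background shares of SMC1B, SALL4, RARB, ZGLP1 and POU5F1 are not given here, so their values are not set against background. REC8, detected in 38.9% (23.1 to 56.5) and 83.7% (74.8 to 90.4), REC114, in 50% and 39.8%, HSF2BP, in 27.8% and 37.8%, ZCWPW1, in 16.7% and 28.6%, and LIN28B, in 2.78% and 2.04%, went against their CPM, so no order is read from them. SALL4 was detected in 16.7% and 35.7%, RARB in 19.4% and 17.3%, ZGLP1 in 13.9% and 10.2%, and POU5F1 in 8.33% and 2.04%. STRA8 was detected in 2.78% and 0%, and PRDM1 in 0% and 1.02%, below its 5.83% and 5.90% in stromal-like cells and so at background.

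The same comparison was made for pregranulosa cells, whose median mitochondrial share was 5.41% at E85 and 2.73% at E125, so RNA quality may enter these values too. The compared cells came from nearly separate clusters, 242 of 243 from cluster 11 at E85 and 539 of 588 from cluster 7 at E125. The differences below may therefore mark the library or another choice of cells rather than a change within 1 cell type. AMH, the anti-Mullerian hormone gene, had 1.27 CPM at E85 and 193 CPM at E125, at least 102-fold higher (42.1 to 1261, from 2 UMIs), and CENPF, a kinetochore gene, was at least 77.7-fold higher (32.2 to 964, from 2 UMIs), though at least 12.9-fold (5.27 to 161) without the 44-cell cluster. PRKAR2B, a regulatory subunit of protein kinase A, had 42.4 and 755 CPM, 17.8-fold higher (14.0 to 23.0), and CHGA and PCSK1N, both of secretory granules, were 16.7-fold (10.3 to 29.4) and 21.8-fold (11.0 to 50.6) higher. C4orf48 was 96.7-fold (33.0 to 469, from 3 UMIs), the chymosin gene CYM 29.2-fold (13.3 to 79.7), DPYSL3 27.3-fold (9.27 to 133, from 3 UMIs), TAF10 23.4-fold (15.6 to 37.0) and RAB21 19.7-fold higher, the latter pair being higher in all 6 classes (RAB21 3.61- to 19.7-fold). Lower at E125 were TUBB2B, at least 209-fold (85.1 to 2616, to 2 UMIs), the epithelial keratin gene KRT19, 35.0-fold (22.9 to 55.4), and NR1H4, the bile acid receptor gene, 9.50-fold (7.07 to 12.9). CCND1, a G1 cyclin gene, had 212 and 40.7 CPM, 5.20-fold lower (4.44 to 6.10). GABARAPL1, RASL11A, NRK, NEDD8 and TSPO were 8.19-, 6.79-, 5.78-, 5.71- and 5.52-fold lower. Of 7430 measured genes, 1082 were at least 2-fold higher and 777 at least 2-fold lower, again by size alone. Higher genes were 58.2% of both, 71.3% with TMM (1327 and 533), 72.8% with DESeq2 size factors (1359 and 508) and 64.7% with the mean over cells (1254 and 685), which moved the median log2 ratio of all genes up by 0.19, 0.21 and 0.10. At resolution 2 there were 1430 higher and 700 lower genes, and with separate clustering 877 and 672.

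Cell cycle genes had a median log2 ratio of 1.34 in E125 pregranulosa-like cells (percentile 100), with 13 higher and 0 lower of 17, and 0.98 without doublet removal and 0.88 with the stricter filter. TOP2A, DNA topoisomerase of dividing cells, was at least 55.6-fold higher (29.9 to 6602, from 1 UMI), TPX2 10.8-fold (5.45 to 25.3) and the helicase gene MCM7 2.21-fold. Follicular granulosa genes had a median of 0.75 (percentile 99.9), with 6 higher and 0 lower of 13, and HSD17B1, an enzyme of oestradiol synthesis, had 84.9 and 524 CPM, 6.18-fold higher (5.20 to 7.40). The bootstrap interval of that list median over members was -0.37 to 2.07, which spans 0. Stromal-like cells had a like median of 0.78 (percentile 93.5), with 3 higher and 1 lower of 9. Medians were 0.27 in germ-cell-like, 0.04 in endothelial-like and -0.27 in surface-epithelium-like cells. The positive median of the follicular granulosa list is therefore not specific to pregranulosa-like cells. TGF-beta and BMP genes had a median of 0.81 (percentile 100), with 11 higher and 0 lower of 26. FST, the activin antagonist follistatin, had 182 and 1408 CPM, 7.75-fold higher (6.89 to 8.74), INHA, an inhibin subunit, 111 and 242 CPM, 2.18-fold (1.87 to 2.56), and ID1 13.9 and 195 CPM, 14.0-fold (9.18 to 22.3). ID1 was also higher in germ-cell-like, stromal-like, surface-epithelium-like and endothelial-like cells, so its difference is not specific to this class. AMH, FST, HSD17B1 and INHA lead the 44-cell E125 cluster, and without it their ratios were at least 94.4 (39.1 to 1170), 7.34 (6.52 to 8.28), 5.70 (4.79 to 6.82) and 2.12. That cluster carried much of the cell cycle genes, and without it TOP2A was at least 9.10-fold higher and the median of the list was 0.85. With the 338 cells of resolution 2 and the 245 of separate clustering, AMH was at least 116- and at least 250-fold, FST 6.99- and 14.9-fold, HSD17B1 6.70- and 15.2-fold, INHA 1.68- and 3.68-fold and CENPF 19.1- and at least 243-fold higher. The directions of these genes held and their sizes depend on which cells are counted. AMH, FST, HSD17B1 and INHA are also markers that name the class, so they enter the choice of cells. Their directions do not speak for the other named genes. Pregranulosa regulators had a median of 0.73 (percentile 99.8), with 5 higher and 3 lower of 15. IRX3, IRX5 and ZNRF3 were 5.90-, 5.01- and 8.48-fold higher and CTNNB1 2.33-fold lower, while WT1 had 219 and 252 CPM. The regulator list also had positive medians in endothelial-like (0.78), surface-epithelium-like (0.66), stromal-like (0.61) and germ-cell-like cells (1.14). Its positive median is therefore not specific to pregranulosa-like cells. WNT genes had a median of 0.39 (percentile 97.1), with 4 higher, among them RSPO3 at 3.1-fold, and 1 lower, LEF1 at 2.55-fold, of 15. Extracellular matrix genes had a median of 0.42 (percentile 98.8), with 3 higher, including MGP at 11.4-fold and FBLN1 at 2.58-fold, and 3 lower, including MFAP2 at 3.28-fold, of 22.

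Oxidative phosphorylation genes had a negative median in E125 pregranulosa-like cells, -0.53 (percentile 0.7). Of 14 measured, 0 were higher, 11 within 2-fold and 3 lower, namely COX8A, NDUFA2 and UQCRQ. Oocyte genes had a median of 1.02 (percentile 98.4), with 5 higher and 0 lower of 7, at low levels such as 8.23 and 41.7 CPM of ZP3, and the sign reversed to -2.17 under 2 of the other naming rules. Steroidogenesis genes had a median of 0.34 (percentile 85.5), with 3 higher and 1 lower of 10, among them FDX1 at 13.3-fold higher, while the aromatase gene CYP19A1 had 69.0 and 41.5 CPM. That median was -0.22 in thinned cells and -0.15 with the stricter filter. KIT and PI3K genes had a median of 0.21 (percentile 81.5), with FOXO1 2.89-fold higher and TSC2 2.22-fold lower of 12. The median was -0.01 under 2 of the other naming rules. Cholesterol synthesis genes had a median of -0.20 (percentile 31.0, 0.01 with DESeq2 size factors), with 0 higher and 2 lower of 12, of which MSMO1 had 760 and 258 CPM. With separate clustering that median was 0.49. Notch genes had a median of -0.24 (percentile 37.8), with 0 higher and 1 lower of 10, HEY1 at 6.45-fold, and apoptosis genes -0.47 (percentile 18.3), with 0 higher and 2 lower of 13, BCL2 at 3.77-fold and CASP6 at 3.07-fold. In thinned cells both of these medians were positive, at 0.33 and 0.19, and Notch was also positive at resolution 2 (0.06) and with separate clustering (0.23). Dissociation stress genes had a median of -0.17 (percentile 28.5), with JUN 6.85-fold and DUSP1 3.11-fold higher and 4 lower of 13, and TMM and DESeq2 size factors turned it to 0.02 and 0.05 and resolution 2 to 0.50. Glycolysis genes had a median of 0.13 (percentile 79.6), with 0 higher and 1 lower of 11, and it was -0.10 with the stricter filter and -0.05 without the small E125 cluster. Germ meiotic prophase genes had a median of -0.46 (percentile 13.2), with 3 higher and 1 lower of 11, piRNA genes 0.52 (percentile 82.3), with 1 higher and 1 lower of 3, and testis supporting or Leydig genes 0.43 (percentile 84.6), with 1 higher, AMH, and 0 lower of 4. The mean over cells gave 0.03 for meiotic prophase, the stricter filter -0.16 and resolution 2 -0.28 for piRNA, and a minimum of 50 UMIs -0.06 and separate clustering -0.42 for the testis list. The mitotic and meiotic entry lists had 1 measured gene each and no median.

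Stromal-like cells, the largest class, had 1832 genes at least 2-fold higher and 1129 at least 2-fold lower at E125 of 10239 measured. SPON2, which encodes a secreted matrix protein, had 9.12 and 405 CPM, 44.4-fold higher (35.4 to 56.5), CDC42EP5 was 133-fold higher (56.9 to 411), and C4orf48, PODXL2 and GAS6, the ligand of TAM receptors, were 77.7-, 46.9- and 31.2-fold higher. Lower were TUBB2B at 33.8-fold, the neuropeptide Y gene NPY at 12.4-fold, WFDC2 at 10.3-fold, CDC23 at 8.93-fold and NELL2 at 8-fold. The 61.9% of higher genes moved to 65.4% with TMM and 66.0% with DESeq2 size factors. Surface-epithelium-like cells had 990 higher and 555 lower of 7151, with GBP5, an interferon-induced GTPase gene, at 0 and 374 UMIs, at least 63.0-fold higher. PODXL2 was at least 39.1-fold (16.1 to 487, from 2 UMIs), C4orf48 29.7-fold, GAS6 20.2-fold and TAF10 19.7-fold higher there, and TUBB2B was at least 110-fold (to 2 UMIs) and LRRTM3, ASPN, MSMO1 and GPX4 were 10.9-, 7.36-, 4.67- and 4.64-fold lower. Endothelial-like cells had 1350 higher and 519 lower of 6996, with CDC42EP5 24.5-fold (9.55 to 90.2), SMAP1 and ZNF444 both 19.3-fold, HDGF 16.3-fold and CHCHD10 15.9-fold (5.42 to 77.6) higher. GAP43, a growth cone gene, was 21.7-fold lower, TUBB2B 13.8-fold, the immediate early gene FOS 7.93-fold (717 and 90.4 CPM), MEOX1 7.23-fold and DCTN3 4.89-fold. Myeloid-like cells had 336 higher and 185 lower of 2054. The osteopontin gene SPP1 went from 602 to 5 UMIs, 146-fold lower (62.1 to 450), GPNMB from 196 to 0 UMIs, at least 79.1-fold lower, and SBSN from 58 to 0 UMIs, at least 23.4-fold lower, while the galectin gene LGALS3 was 27.7-fold (13.8 to 65.1) and the scavenger receptor gene CD36 12.5-fold (6.51 to 26.8) lower. BATF3 was 22.8-fold higher (11.4 to 53.5) in myeloid-like cells. SMAP1, CHPT1, MAN1A1 and SMARCC1 were 28.1-fold (9.35 to 139), 22.3-fold (7.37 to 110), 22.0-fold (7.28 to 109) and 19.8-fold (6.52 to 98.4) higher, each from 3 UMIs at E85, and SMAP1, CHPT1 and MAN1A1 were past 2-fold in all 6 classes.

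The last comparison asked which classes held ligands and receptors of oocyte and granulosa signalling. KITLG, AMHR2 and BMP2 are also naming markers of pregranulosa-like cells, and NOTCH3 of perivascular-like cells. Their levels in those classes are therefore partly set by the naming. KITLG, the ligand of KIT, had 166 CPM (146 to 187) and 201 CPM (191 to 211) in pregranulosa-like cells at E85 and E125, and 377 CPM (329 to 430) and 202 CPM (190 to 213) in endothelial-like cells. Surface-epithelium-like cells held it too, at 231 CPM (212 to 252) and 124 CPM (114 to 135). KIT was in germ-cell-like cells, at 154 CPM (136 to 175) and 132 CPM (124.9 to 139), and in endothelial-like cells at 85.3 and 125.4 CPM, with 1.27 and 2.80 CPM in pregranulosa-like cells. JAG1 had 390 and 252 CPM in germ-cell-like cells, 162 and 250 CPM in endothelial-like cells and 821 CPM in perivascular-like cells at E125. NOTCH3 had 1543 CPM in E125 perivascular-like cells, against 61.9 and 96.5 CPM in stromal-like cells and 41.8 and 33.7 CPM in pregranulosa-like cells, and NOTCH2 had 17.7 and 15.1 CPM in pregranulosa-like cells. JAG2 had 130 and 270 CPM in endothelial-like cells. BMP15, an oocyte growth factor gene, had 8.57 and 34.6 CPM in germ-cell-like cells and GDF9, its paralogue, 11.6 and 4.15 CPM. BMPR1B had 105 and 78.7 CPM in germ-cell-like cells and 52.6 and 93.1 CPM in pregranulosa-like cells, and AMHR2, the AMH receptor gene, 6.97 and 3.87 CPM in pregranulosa-like cells. BMP4 and BMP2 were in surface-epithelium-like cells, BMP4 at 27.8 and 65.7 CPM and BMP2 at 15.0 and 42.9 CPM, and ACVR1 in endothelial-like cells at 75.1 and 117 CPM.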

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

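The 3 other naming rules, the limit to large germ-cell-like droplets, the set without the small E125 pregranulosa-like cluster and the use of other clusterings for gene counts and lists were chosen after the data were seen. Shares of all classes stayed within their 95% interval in 161 cases and moved in 55, counts of genes stayed within 1.5 times in 76 and moved in 18, germ-cell-like list medians stayed within their interval over members (2000 bootstrap draws) in 247 and moved in 22, and pregranulosa-like ones stayed in 233, moved in 13 and reversed in 2, while stage marker shares stayed in 15 and moved in 49. Where a value moved, the cause was not tested, except that higher UMI minimums, thinning and leaving out free-RNA genes lower counts by construction. Genes past 2-fold: DESeq2 size factors gave 1092 lower in germ-cell-like and 508 lower in pregranulosa-like cells, TMM 1074 lower in germ-cell-like cells, and the mean over cells 2957 higher. Thinning gave 218 higher and 115 lower of 943 genes in germ-cell-like cells and 527 and 259 of 3503 in pregranulosa-like cells. Without free-RNA genes 1176, 639 and 1062 were higher in germ-cell-like, pregranulosa-like and stromal-like cells. A minimum of 20 UMIs gave 1297 lower in pregranulosa-like cells, and one of 200 gave 946 higher and 767 lower, 553 and 276, and 1129 and 570 in the 3 classes. Large germ-cell-like droplets alone (1690 and 1634) and the other clusterings moved no count past 1.5 times. List medians (log2): in germ-cell-like cells follicular granulosa went to 0.53 with DESeq2 and 0.54 with TMM. The mean over cells gave TGF-beta and BMP 1.18, apoptosis 0.30, cholesterol synthesis 0.30, extracellular matrix 1.20, follicular granulosa 0.75, oocyte 1.45 and piRNA -0.87 there, and extracellular matrix 0.78 in pregranulosa-like cells. Thinning gave Notch -0.0044, cell cycle 0.56 and oocyte 0.84 in germ-cell-like cells, and Notch 0.33, apoptosis 0.19 and extracellular matrix 0.85 in pregranulosa-like cells. The pregranulosa-like cell cycle median was 0.98 without doublet removal, 0.88 with the stricter filter and 0.85 without the small E125 cluster. Naming by fold over other cells, and by other thresholds, reversed the pregranulosa-like oocyte median to -2.17 and -2.17 and put 8.21% and 8.21% of E85 cells in that class, by adding the unnamed E85 cluster of 71 cells to it. Naming by fold over other clusters gave germ-cell-like medians of -0.99 for extracellular matrix, -0.59 for follicular granulosa, -0.58 for glycolysis and 0.13 for steroidogenesis, and resolution 0.5 and separate clustering gave -1.02 and -0.92, -0.39 and -0.37, and -0.52 and -0.57 for the first 3 of these lists. In pregranulosa-like cells resolution 2 gave TGF-beta and BMP 1.26 and dissociation stress 0.50, and separate clustering gave cholesterol synthesis 0.49, oocyte 2.44, glycolysis 0.57 and testis supporting or Leydig -0.42. Class shares (%): naming by fold over other clusters gave 3.14 germ-cell-like at E85 and 27.6 stromal-like at E125. Separate clustering gave 3.14 germ-cell-like and 68.9 stromal-like at E85 and 3.49 pregranulosa-like and 64.1 stromal-like at E125. No filter gave 3.63 and 67.6 for the same at E85, and 3.07 germ-cell-like, 62.7 stromal-like and 9.94 endothelial-like at E125. No doublet removal gave 63.9 stromal-like at E125, resolution 0.5 gave 2.75 germ-cell-like at E85, and resolution 2 gave 70.4 stromal-like at E85 and 4.81 pregranulosa-like and 48.8 stromal-like at E125. The stricter filter gave 0.949 germ-cell-like and 8.54 pregranulosa-like at E85 and 12.7 pregranulosa-like, 66.0 stromal-like and 12.3 endothelial-like at E125. Surface-epithelium-like cells at E125 were 2.02 with no filter, 1.16 with the stricter filter and 3.15 at resolution 2, and steroidogenic-like cells there 0.239 without doublet removal, 5.11 at resolution 2 and 4.86 with separate clustering. Glia-like cells were 2.27 and 2.33 at E85 at resolution 2 and with separate clustering and 0.773 at E125 with the stricter filter. Lymphoid-like cells were 2.22 at E85 with separate clustering, 0 and 0 at resolution 0.5, and 0 at E125 under naming by other thresholds. Myeloid-like cells were 1.98 at E85 with the stricter filter and 2.12 and 2.86 at resolution 0.5, and perivascular-like cells 1.20 at E125 with the stricter filter. Unnamed cells at E85 were 11.6 with no filter, 5.14 with the stricter filter, 5.75 at resolution 0.5, with separate clustering and when named by fold over other cells or by other thresholds, and 5.83 when named by fold over other clusters. At E125 they were 7.86 with no filter, 1.20 with the stricter filter, 4.17 without doublet removal, 0 at resolution 0.5, 19.9 at resolution 2, 4.27 with separate clustering, 40.7 when named by fold over other clusters and 1.44 when named by other thresholds. Stage markers in germ-cell-like cells (% of cells, E85 and E125): without thinning HSF2BP 69.4 and 75.2, LIN28B 18.4 and 49.6, POU5F1 44.9 and 48.8, PRDM1 14.3 and 24.0, RARB 46.9 and 59.7, REC114 69.4 and 70.5, SALL4 46.9 and 70.5, SMC1B 81.6 and 69.0, ZCWPW1 46.9 and 70.5, ZGLP1 42.9 and 59.7, STRA8 5.43 at E125 and ZP3 93.9 at E85. With 2 or more UMIs FIGLA 25.0 and 90.8, HSF2BP 8.33 and 6.12, LIN28B 0 and 0, POU5F1 0 and 0, RARB 5.56 and 1.02, REC114 16.7 and 10.2, REC8 22.2 and 49.0, SALL4 0 and 14.3, SMC1B 25.0 and 9.18, UCHL1 52.8 and 76.5, ZCWPW1 5.56 and 9.18, ZGLP1 0 and 0, ZP4 67.3 at E125, STRA8 0 at E85 and PRDM1 0 at E125.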

Other observations

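Tests on deeper sequencing, on the share of small droplets, on damaged cells, on free RNA outside pregranulosa-like droplets and on the unnamed E85 cluster of 71 cells were chosen only after the results were seen, as was the first form of the doublet test, while those on somatic cells and on free RNA in all classes were written before.

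Outside the germline and its partners, endothelial-like cells at E125 had positive medians of the cell cycle and extracellular matrix lists. Their cell cycle list had a median log2 ratio of 1.15 (percentile 100), with 10 higher and 0 lower of 19, CENPF at 8.85-fold and TOP2A at 7.43-fold. Their matrix list had a median of 0.99 (percentile 100), with 11 higher and 0 lower of 23, including the collagen IV genes COL4A1 at 2.45-fold and COL4A2 at 3.94-fold, and ID1 was 15.9-fold higher. Their Notch list had a median of 0.62 (percentile 99.4), with 3 higher (JAG2 2.08-fold) and 1 lower (HEY1 2.56-fold) of 14, and their dissociation stress list -0.69 (percentile 0.21). Myeloid-like cells also had a raised cell cycle list, 1.29 (percentile 99.9), with 8 higher and 0 lower of 15. Stromal-like cells did not, at 0.05 with 0 higher and 1 lower of 21.

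In stromal-like cells the matrix list had a median of 0.62 (percentile 100), with 12 higher and 5 lower of 31, among them MGP, a calcification inhibitor gene, at 57.0 and 1710 CPM and COL1A2 at 565 and 1379 CPM, while POSTN and LUM were 5.49- and 2.16-fold lower. In surface-epithelium-like cells the same list went the other way, -0.53 (percentile 0.08), with 2 higher and 6 lower of 23, COL1A1 and POSTN 7.15- and 13.1-fold lower among them. The TGF-beta and BMP list had positive medians in both classes, 0.78 (percentile 100) with 12 higher and 0 lower of 31 in stromal-like cells and 1.04 (percentile 100) with 15 higher and 1 lower of 28 in surface-epithelium-like cells. ID1 was 36.1- and 23.8-fold higher there. WNT genes stood at 0.84 (percentile 99.9) in stromal-like cells, with SFRP1 7.03-fold and WNT5A 2.60-fold higher. Oxidative phosphorylation genes had negative medians in all 6 compared classes, -0.76 in stromal-like, -0.54 in endothelial-like, -0.57 in myeloid-like and -0.38 in surface-epithelium-like cells beside the values given for the other 2, though only 15 of the 33 genes of that list have a symbol. TMM and DESeq2 size factors move all ratios of a class alike, in these last 4 classes at most by the myeloid-like TMM factors of 0.942 and 1.06, and turn the sign of none of these medians, while the other alternatives were not run on lists in these 4 classes.

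Germ-cell-like droplets held more UMIs at E125 than at E85. Deeper sequencing would raise other classes alike, but the median of their UMI ratios was 1.01. Over all classes, droplets of 20000 or more UMIs numbered 49 of 3825 kept cells at E85 and 270 of 7023 at E125. Of these, 22 and 71 were germ-cell-like, so large droplets were also more numerous in other classes at E125, for a reason not tested. A larger share of small droplets at E85 stays open, since the ratio of medians at or above a UMI limit was 2.48 for limits of 10000 and 20000 but 1.45 for 40000, under the bound of 1.5, with 12 droplets at E85, and so does damage of E85 germ cells, since large droplets had a median mitochondrial share of 5.43% at E85 and 2.13% at E125 and their ratio was 2.00 among droplets under 10% but 1.37 under 5% (8 and 61 droplets). Somatic cells caught in the same droplets would bring their markers at the level of a whole cell. The median marker of the highest of 3 lists reached 0.595 of it (0.549 for stromal and 0.0787 for endothelial markers). These values average over large and small droplets, and the 71 large ones of 129 at E125 held 98.4% of the class UMIs. The level in the large droplets may therefore be higher, and somatic cells in them are not excluded. Growth of the oocyte with age, or more pairs of germ cells in a droplet, could give such a difference and neither was tested, and with 1 library per stage a difference between animals or preparations stays open.

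Germ cell genes also had UMIs outside the germ-cell-like class at E125, where 15 of them summed to 1643 UMIs per germ-cell-like droplet. Free RNA in equal amounts per droplet would reach every somatic class alike, but pregranulosa-like droplets held 5.34 UMIs and myeloid-like droplets 1.07, a ratio of 4.99 (4.11 to 6.11), which exceeds the limit of 4 set beforehand only narrowly at its lower bound. That interval does not allow for the choice of the highest and lowest class. Among the classes other than pregranulosa-like the ratio was 3.68, from 3.94 UMIs in surface-epithelium-like droplets, and the other 6 lay between 1.07 and 1.88, so free RNA stays open there. Free RNA that scales with a droplet's own RNA is not excluded in any of the classes. In CPM the span was 197 in myeloid-like to 525 in glia-like cells, a ratio of 2.66 and under the limit of 4. Pregranulosa-like cells had 418 CPM. Leftover pairs of germ and pregranulosa cells, or pieces of oocyte attached to their neighbours, may add to the UMIs outside the germ-cell-like class and were not tested. The positive oocyte medians in somatic classes, 2.38 in stromal-like and 1.64 in surface-epithelium-like cells, are therefore not read as expression there.

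An unnamed E85 cluster of 71 cells, clustered together with the 44 E125 pregranulosa-like cells led by HSD17B1 and FST, had oocyte genes without most germ cell markers. ZP3 stood at 3047 CPM, ZP4 at 695 CPM and FIGLA at 128 CPM in it, beside KRT17 at 227 CPM (library 5.34), KRT8 at 349 CPM (library 64.0) and CDKN1A at 439 CPM (library 58.9), while DDX4 had 16.0 CPM against 369 CPM in germ-cell-like cells. A large germ cell with another cell would hold at least its UMIs, but the cluster's median was 0.0631 of that of large germ-cell-like droplets (a first comparison with the whole class gave 0.415 and was replaced because that class mixes large and small droplets). RNA of a small germ-cell-like droplet with another cell would keep the other markers in proportion to ZP3, whereas 13 of them reached 0.187 of it (0.150 to 0.233). Germ cells of another state, stressed or degrading oocytes among them, or a somatic type that holds zona RNA, could each give this cluster, and none was tested.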
